A study of Mus musculus with 15 samples.

How the data were processed

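The 15 samples in the labels were mouse macrophage libraries: biotin ChIP-seq of tagged RevErbalpha, tagged RevErbbeta and BirA in RAW cells, GRO-seq of floxed and Tie2-Cre floxed bone marrow derived macrophages, 5'GRO-seq of control and tagged RevErbalpha RAW cells, and ChIP-seq of H3K9ac, H3K4me1 and PU.1. Values per library for H3K9ac, H3K4me1 and PU.1 were not analysed here. Each group in the labels has 1 sample.

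The authors deposited 4 tables: a list of 1544 peaks common to RevErbalpha and RevErbbeta, its part with high H3K4me1 and low H3K4me3, the intergenic part of that, and a summary table with values at each common peak. Reads were mapped to mm9, and Bowtie 0.12.7 and HOMER are named, per the submitters' processing notes. Peak calling settings and the cut-offs for histone marks were not given in the sources used here. Values at peaks are log2 tags per 10000000, counted in 157 bp for ChIP-seq and 500 bp for 5'GRO-seq, per the file headers. The deposited log2 values were checked at low levels and were not on steps of whole tags. Their remainders were spread evenly over a tag, as if a random part below 1 tag had been added before scaling. The scaling factor was 14.65 and 16.71 in RevErbalpha runs 2 and 3, so such a part would weigh most in the shallow runs. They were therefore not treated as counts. GRO-seq values at peaks and genes are also log2 values per the file headers, which give the total of each gene-level run and a scaling factor of 1 but no further scaling. WT and DKO values at peaks were given as 1 column each. The column named BirA-input was read as the BirA ChIP-seq library of the labels, and its name could also stand for an input library. The header of the summary table also lists treated libraries, and the columns do not tell whether any run was treated.

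Means of runs and differences between libraries were recomputed from the columns and lay within 0.01 of the authors' own mean and difference columns. No column of per-sample values was left unused. The 3 runs per RevErb and 2 per genotype were averaged on the log2 scale and counted as 1 replicate. Peak class, distance to a gene start and assigned gene were the authors'. The assigned gene is the nearest expressed one per the file headers, from a list of starts not used here. Gene IDs were paired with symbols through a RefSeq table of assembly GRCm38.p6, used for names only, in which 1208 of 1220 IDs matched. Names that a spreadsheet had turned into dates, at 3 peaks, were replaced by the RefSeq symbol. The gene IDs of 57 peaks are of non-coding transcripts.

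Depth ranged from 598490 to 5276592 tags for RevErb runs. At the median peak this was about 16.6, 3.6 and 2.8 tags in the RevErbalpha runs, 16.5, 41.2 and 2.8 in the RevErbbeta runs and 0.71 in BirA. The median peak held about 123 and 38.3 tags in the control and tagged RevErbalpha 5'GRO-seq libraries, and 86 and 172 peaks held none. No tag counts could be taken from the GRO-seq columns, so their counting error is unknown.

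Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Location was compared with 2-sided Fisher's exact tests. Binding of enhancer-like and other peaks was compared with 2-sided permutation tests of the difference in medians (100000 resamples). Medians across peaks have bootstrap 95% intervals from 10000 resamples, which cover the spread across peaks in 1 pair of libraries. Peaks and genes are not independent replicates, and correlations across them are given without p-values. Gene lists near peaks were tested with 2-sided Fisher's exact tests against the protein-coding genes of the RefSeq table. In comparisons between conditions, which have 1 sample each, values are shown per run where the table gives runs, and a gene was counted as higher or lower when its difference was at least 0.5 on the log2 scale and the runs of the genotypes did not overlap. For peaks a difference of 1 was used. The gene-level comparison of genotypes, the binding groups, the list percentiles and both size rules were set after the tables had been seen. List medians are given as percentiles among 10000 random lists whose members were drawn from the 50 genes nearest in level. For the peaks of lists and of higher genes, random genes with as many peaks (3 or more taken as 1 group) were drawn, which keeps peaks of 1 gene together.

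The gene rule, the permutation test, the random lists of genes and the bootstrap were tested on simulated data. Of 200 genes among 1220 changed by 1 on the log2 scale, with the real spread between runs, the gene rule recovered 97.1%, and it called 29.3 unchanged genes on average over 20 draws. The permutation test gave p under 0.05 in 4 of 100 unchanged draws and in 100 of 100 with a shift of 0.3. Of 100 unchanged lists 6 lay outside the central 95% of random lists, and 97 of 100 lists shifted by 0.2 lay above. Bootstrap intervals held the true median in 95.5% of 200 draws.

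Genes and peaks to be named were chosen by a rule set before the data were examined: the 10 strongest common peaks, the genes with the most common peaks (10, ties kept), up to 5 members of each list ranked by peak value, Cx3cr1, Mmp9, Arntl, Nr1d1 and Nr1d2 whatever they showed, and the 5 strongest intergenic enhancer-like peaks. Some genes that the rule names are not reported here. Other names are said to have been chosen after. Alternatives set before the data were examined were a larger offset before the logarithm (10 in place of 1), a filter on low signal at peaks, the stronger part of the peaks, other distances to a gene start, ranks in place of values, and matching of lists by overlap. Alternatives added later were the deeper runs alone, 4 binding groups in place of 5, leaving out each GRO-seq run, shifting the runs to the same median, genes above the lower quartile of level, the larger offset by class, intergenic enhancer-like peaks of the higher genes, leaving out named genes, and the random genes with as many peaks. Planned counts of peaks bound by 1 RevErb alone, tests of those peaks against common peaks and random draws for spacing were not run, since the tables used here list common peaks. Genic and intergenic shares of the peaks outside the enhancer-like list were not compared, since the authors' class does not separate them. Motifs were not analysed here, since no genome was used. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.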

Results

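The series measured where the nuclear receptors RevErbalpha (gene Nr1d1) and RevErbbeta (gene Nr1d2) bind in mouse macrophages and how nascent transcription differs when they are gained or lost. RevErbs are transcriptional repressors of the circadian clock. Binding was measured in RAW macrophages, a mouse macrophage cell line, that carried RevErbalpha or RevErbbeta with a biotin tag, so that the tagged protein could be pulled down on streptavidin beads. A library from cells with BirA, the biotin ligase, was read as the background, although its column is named BirA-input and an input library in place of a pull-down is not ruled out. Nascent RNA was measured by GRO-seq, which reads RNA still being made by RNA polymerase, in bone marrow derived macrophages with floxed alleles of both genes (WT) and with the same alleles plus Tie2-Cre (DKO). It was measured by 5'GRO-seq, which reads the 5' ends of capped nascent RNA, in control RAW cells and in RAW cells with tagged RevErbalpha. The labels list 15 samples, each the 1 sample of its group, and 7 of them have values in the tables used here. The tables held 3 ChIP-seq runs for each RevErb and 2 gene-level GRO-seq runs for each genotype, which were treated as repeat runs of 1 sample. The column names number the runs but do not tell whether they are separate cell preparations or whether any run was treated. Gene values differed between the 2 WT runs with an SD of 0.34 and between the 2 DKO runs with an SD of 0.30. Counted as 1 sample per group, no difference between conditions has a replicate check, and none is given a p-value. The RevErbalpha runs had 5276592, 682651 and 598490 tags, the RevErbbeta runs 3751878, 4888686 and 780281, and the BirA library 10548880. The 5'GRO-seq libraries had 18708148 tags in control cells and 7238710 with tagged RevErbalpha. The gene-level GRO-seq runs had 38010000 and 43560000 tags for WT and 46650000 and 34850000 for DKO. Positions are on mouse build mm9.

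The first comparison asked what kind of site RevErbalpha and RevErbbeta share. The authors listed 1544 peaks common to both proteins, and most of them carried the histone marks of enhancers rather than promoters. High H3K4me1 with low H3K4me3 marked 1243 of the 1544 peaks (80.5%, exact Clopper-Pearson 95% interval 78.4 to 82.5%). Of these enhancer-like peaks, 687 lay in the authors' genic class and 556 in their intergenic class, which were 44.5% and 36.0% of all common peaks. The other 301 peaks (19.5%) were in neither list, and the authors' class for them reads H3K4me3 above H3K4me1. These 301 sites lay at gene starts far more often: 152 of 301 were within 1 kb of a start in the authors' gene list, against 0 of 1243 enhancer-like peaks (2-sided Fisher's exact test across peaks, p = 1.1e-125). The nearest enhancer-like peak was 1057 bp from a start, and whether a distance limit went into the list is not stated in the sources used here. The classes were set by histone marks of enhancers and promoters, so a difference in location was in part built into them. The p-value is therefore no separate finding about RevErb sites. Within 2.5 kb the counts were 184 of 301 and 45 of 1243. The median distance to a start was 24142 bp for genic enhancer-like peaks, 33652 bp for intergenic ones and 990 bp for the rest. Common peaks lay near one another in part: 546 of 1544 (35.4%) had another common peak within 50 kb.

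The authors assigned the peaks to 1220 gene IDs, which have 1205 gene symbols. Each ID was counted as 1 gene throughout, so a gene with several IDs counts more than once. Of the 1220, 982 had 1 peak, 172 had 2 and 66 had 3 or more. Spred1, an inhibitor of Ras and MAP kinase signalling, had the most with 9 common peaks, followed by Reep3 with 6 and Lpp with 5. Cited2, Cyth4, Emp1, Enpp6, Irf2bp2, Irf2bpl, Itpkb, Plxna1 and Tgm2 had 4 each. Listed genes of macrophage identity and function were frequent among the assigned genes. Of the 28 macrophage transcription factors listed before the data were examined, 15 had a common peak, among them Hif1a, Runx1, Fos and Irf5 (Fisher's exact, adjusted p = 1.6e-11). The extracellular proteases and inhibitors followed with 10 of 22, including Mmp9, Adam17, Plaur and Ctss (Fisher's exact, adjusted p = 3.6e-07). The clock list had 8 of 24, including Arntl, Npas2, Cry1, Clock and Nr1d1 itself (Fisher's exact, adjusted p = 6.3e-05). Chemokines, cytokines and their receptors had 10 of 32, including Cx3cr1, Tgfbr1, Ccl3, Csf1r and Il10ra (Fisher's exact, adjusted p = 1.5e-05). Pattern recognition genes had 9 of 33, including Nlrp3, Myd88, Tlr4, Tlr2 and Ticam1 (Fisher's exact, adjusted p = 9.3e-05), and lipid genes 8 of 28, including Plin2, Lpcat3, Lrp1, Cd36 and Abca1 (Fisher's exact, adjusted p = 0.00015). The surface and phagocytosis list had 4 of 19 (Itgb2, Axl, Fcgr1 and Tyrobp, Fisher's exact, adjusted p = 0.028) and the cofactor list 3 of 13 (including Tbl1xr1 and Ncoa3, Fisher's exact, adjusted p = 0.043). Neither of these 2 passed the threshold within 10 kb of the start (Fisher's exact, adjusted p = 0.094 and 1.0) or with the stronger peaks (Fisher's exact, adjusted p = 0.15 and 0.090). The housekeeping list had 1 of 14 (Fisher's exact, adjusted p = 0.71). None of the 16 hepatocyte, 17 lymphocyte and 16 muscle and neuron genes had a common peak, which is no contrast to the macrophage lists because peaks were assigned to expressed genes only. Nr1d2 had no assigned common peak in the table. The tests were 2-sided Fisher's exact tests against 21900 protein-coding genes, of which 1161 (5.3%) had a common peak, with Benjamini-Hochberg adjustment over the 12 lists. For the same reason the background holds genes that could not have been assigned a peak, so the tests do not separate RevErb binding from expression in macrophages.

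RevErbalpha and RevErbbeta bound the common peaks with moderately correlated rank orders. The strongest peak by the mean of both proteins was assigned to Slc37a2 (chromosome 9, 37043675 to 37043831), with a mean log2 value of 9.51 against 0.44 for BirA. It was followed by peaks assigned to Sap25 (9.29), Arhgap25 (9.17), Mmp9 (9.11), Pqlc1 (8.86), Dnttip2 (8.84), Zfp236 (8.81), Senp6 (8.71), Hnrnpl (8.63) and Hmga1 (8.63). The Mmp9 peak (chromosome 2, 164768385 to 164768541) lies 5288 bp upstream of the start of Mmp9, a secreted gelatinase, and was the strongest of the intergenic enhancer-like peaks. The next of these were assigned to Dnttip2, Hmga1, Kansl2 (8.61) and AI467606 (8.49). Across all common peaks the median log2 value was 5.45 for RevErbalpha, 5.68 for RevErbbeta and 1.10 for BirA, at peaks that were called for enrichment. The proteins' values had a Pearson correlation of 0.71 and a Spearman correlation of 0.65 across 1544 peaks, which are not independent replicates. RevErbbeta was higher at 1020 peaks, with a median log2 difference of 0.29 (bootstrap 95% interval across peaks 0.24 to 0.33). Spearman correlations between single runs were 0.25 to 0.39 among RevErbalpha runs, 0.47 to 0.59 among RevErbbeta runs and 0.32 to 0.54 between runs of the 2 proteins. Among the deeper runs the value was 0.59 between RevErbbeta runs 1 and 2, and 0.35 and 0.52 between these and RevErbalpha run 1. Only 1 RevErbalpha run was deep, so single runs could not show whether rank orders set the proteins apart. The shallow runs held few tags: a median of about 3.6 and 2.8 tags per peak in RevErbalpha runs 2 and 3, and 2.8 in RevErbbeta run 3. Whether the runs also differed in treatment could not be told from the columns. With only the deeper runs, the Spearman correlation of the proteins was 0.49 and RevErbbeta was higher by a median of 0.89. Both values therefore depended on the runs used.

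**Figure D1:**
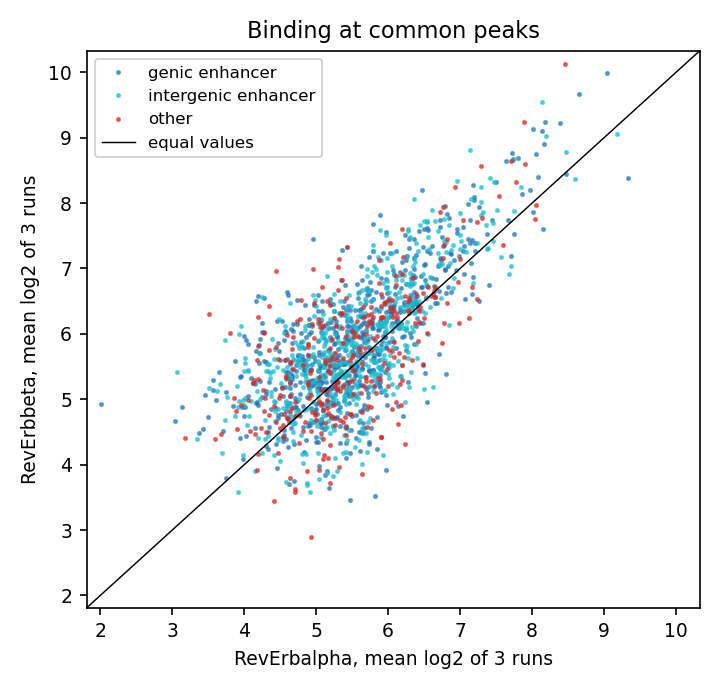
Each point is a common peak, coloured by the authors' class, with the mean log2 normalised tags of 3 RevErbalpha runs on the x axis and of 3 RevErbbeta runs on the y axis. The values rise together (Pearson 0.71), and 1020 of the 1544 points lie above the line of equal values.

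Enhancer-like peaks and the other common peaks had similar median binding, and no test of a difference passed the threshold. The median log2 value, averaged over both proteins, was 5.55 at enhancer-like peaks and 5.48 at the others. RevErbalpha medians were 5.46 at genic enhancer-like, 5.48 at intergenic enhancer-like and 5.37 at other peaks, and RevErbbeta medians were 5.74, 5.68 and 5.61. The difference of 0.068 between enhancer-like and other peaks did not pass a 2-sided permutation test across peaks (p = 0.31). Neither did the separate permutation tests of RevErbalpha (0.10, p = 0.13) and RevErbbeta (0.093, p = 0.27), and the Benjamini-Hochberg adjusted p was 0.31 for all 3. By ranks, the mean rank was 55.6 higher at enhancer-like peaks (permutation p = 0.054). Farther than 1 kb from a start the direction turned, with a difference in medians of -0.15 (permutation p = 0.072).

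The next comparison asked whether transcription at RevErb sites differed when tagged RevErbalpha was present. In RAW cells with tagged RevErbalpha, 5'GRO-seq signal was lower than in control cells at many common peaks, most of all at strongly bound peaks. At the Nr1d1 gene start (chromosome 11, 98636608 to 98636764) the log2 value was 7.97 in control cells and 3.44 with tagged RevErbalpha. At the Mmp9 upstream peak the values were 5.99 and 2.62, and at a peak assigned to Hnrnpl, an RNA-binding protein gene, 5.53 and 0.42. The 3 peaks of Cx3cr1, the fractalkine receptor gene, had log2 differences of -1.51, -2.12 and -0.75. The 3 peaks of Arntl, the clock activator gene, had differences of -1.38, -1.84 and -2.46. The Nlrp3 peak, at an inflammasome gene, had a difference of -1.34 and the Plin2 peak, at a lipid droplet gene, -2.27. Other named sites did not share this direction. The Csf1r peak, at the M-CSF receptor gene, had a difference of 0.16, the Tlr4 start 0.28 and the Tlr2 start 0.35. The Zfp236 peak, which had almost no signal in control cells, had a difference of 2.70. With 10 added before the logarithm in place of 1, the differences shrank to -2.26 at Mmp9, -2.42 at Hnrnpl, -1.07 at the last of the Arntl peaks and 0.64 at Zfp236, and the difference at the Nr1d1 start was -3.71.

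Across all 1544 common peaks the median log2 difference was -0.23 (bootstrap 95% interval across peaks -0.27 to -0.19). Signal was lower by 1 or more at 309 peaks and higher by 1 or more at 76. By class the median was -0.33 at genic enhancer-like peaks, -0.21 at intergenic enhancer-like peaks and -0.09 at the others. The difference followed binding: among 5 groups of peaks ranked by mean binding, the median was -0.06 in the weakest group and -0.56 in the strongest. In the strongest group 237 of 309 peaks were lower, and the 2 groups differed by -0.50 (interval -0.71 to -0.39). Within the strongest group the median was -0.84 for 141 genic enhancer-like peaks (interval -1.07 to -0.51). It was -0.53 for 118 intergenic ones (interval -0.70 to -0.34) and -0.19 for the 50 others (interval -0.535 to -0.08). The last 2 intervals overlapped, and the shares lower by 1 or more were 44.0%, 33.1% and 30.0%. The Spearman correlation with binding was -0.24 across peaks. The counts of peaks fell to 181 lower and 34 higher when 10 was added to the values in place of 1 before the logarithm. The intervals cover the spread across peaks only, since each condition was 1 library.

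**Figure D2:**
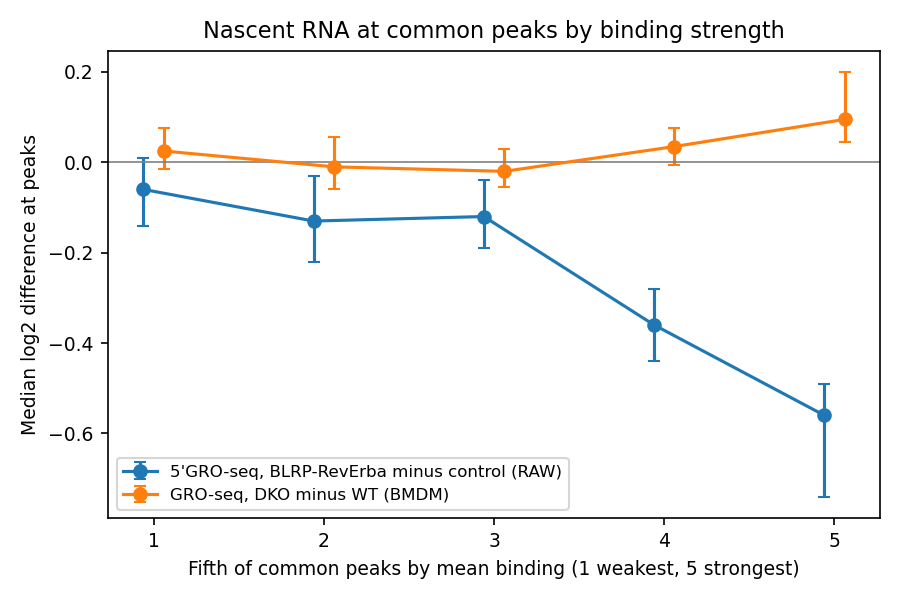
Median log2 difference at common peaks in 5 groups ranked by mean binding of both RevErbs, from 1 (weakest) to 5 (strongest), with bootstrap 95% intervals across peaks as bars. The 5'GRO-seq difference between tagged RevErbalpha and control cells falls from -0.06 to -0.56, and the GRO-seq difference between DKO and WT macrophages is 0.03 in the weakest and 0.10 in the strongest group.

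The libraries labelled WT and DKO were compared in bone marrow derived macrophages, first for the targeted genes. Nr1d1 signal was higher in the library labelled DKO, with log2 values of 7.91 and 7.48 in the WT runs and 9.44 and 9.56 in the DKO runs. These values cover the whole gene and do not show whether its floxed part was removed, so they do not check the labels. Nr1d2 was not analysed here, since the table gives gene values only for genes with a common peak. GRO-seq signal at the common peaks differed little between genotypes. The peaks of Nr1d1 had log2 differences of 1.60, 1.18 and 0.35 in the library labelled DKO relative to WT. The 3 Cx3cr1 peaks had differences of 1.20, 1.39 and 1.40, the 3 Arntl peaks 0.93, 1.13 and -0.18, and the 2 peaks of Npas2, a relative of Clock, 1.36 upstream of its start and 0.15. The Mmp9 upstream peak had a difference of 0.33. With 10 added before the logarithm, the stronger Arntl peaks had 0.46 and 0.29, the upstream Npas2 peak 0.38 and the last Cx3cr1 peak 0.78. Across all 1544 peaks the median was 0.03 (interval 0.00 to 0.05), and it was 0.04, 0.02 and 0.01 in the genic enhancer-like, intergenic enhancer-like and other classes. Signal was higher by 1 or more at 52 peaks and lower by 1 or more at 34, counts that were 3 and 0 when 10 was added before the logarithm. In the strongest of the 5 binding groups the median was 0.10 (interval 0.05 to 0.20), and 188 of 309 peaks were higher. The strongest group exceeded the weakest by 0.07 (interval -0.01 to 0.18), by 0.15 above the lower quartile of signal and by 0.03 with 10 added. Across all peaks the difference had a Spearman correlation of 0.08 with binding (interval 0.03 to 0.13).

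At the level of genes, most genes with a RevErb site differed little between genotypes, and the largest differences were at Nr1d1 and Cx3cr1, which were higher in the library labelled DKO. The log2 difference was 1.81 for Nr1d1 and 1.65 for Cx3cr1, which read 8.19 and 9.16 in the WT runs and 10.24 and 10.40 in the DKO runs. Arntl differed by 1.07 (10.17 and 10.31 against 11.37 and 11.25) and Npas2 by 0.98 (9.47 and 9.30 against 10.38 and 10.34). Mmp9 differed by 1.20, but its WT runs lay far apart at 7.71 and 6.07, and the difference was 0.38 without WT run 2 and 2.02 without WT run 1. Of genes chosen after their values were seen, Tspan33 (1.42), Clec1b (1.15), Ptges (1.02) and Slc15a3 (0.88) were also higher. The first 3 had little signal, with WT means of 4.965, 3.46 and 4.33, against 9.45 for Slc15a3. Tpd52l1 (-1.31) and Mif (-1.03), likewise chosen after, had the largest differences in the other direction, and Mif had -0.27 without DKO run 1 and -1.79 without DKO run 2. Cry1 and Clock, also of the clock, had overlapping runs, with differences of 0.12 and -0.02. Csf1r had 0.10, with overlapping runs, and Runx1, a transcription factor of blood cells, 0.10. Of the genes with the most peaks, Spred1 had -0.12, Reep3 0.00 and Lpp -0.09, each with overlapping runs, while Cited2 (0.40) and Plxna1 (0.36), with 4 peaks each, had both DKO runs above both WT runs. Cited2 had 0.14 without DKO run 2 and 0.65 without DKO run 1, and Plxna1 0.27 to 0.44 with 1 run left out. Of 1220 genes, 24 had a difference of 0.5 or more with both DKO runs above both WT runs, and 9 had a difference of -0.5 or less with both below. Most of these genes had low signal: their median levels were 6.09 and 5.12, against 9.885 for all genes. Only 7 of the 24 and 1 of the 9 lay above the lower quartile of level. Without regard to size, 224 genes had both DKO runs above both WT runs and 122 had both below, where chance gives 16.7% or about 203 in each direction. The splits that mix genotypes gave 208 and 134, and 186 and 296, so an imbalance of this size also arose without genotype. Leaving out WT run 1, WT run 2, DKO run 1 or DKO run 2 gave 63, 52, 67 or 33 higher genes and 27, 19, 17 or 27 lower genes, since fewer runs have to lie apart. Splitting the 4 runs across genotypes gave 31 and 40 genes of that size, against 33 for the real split. The count of genes was therefore not larger than the spread between runs gave.

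**Figure D3:**
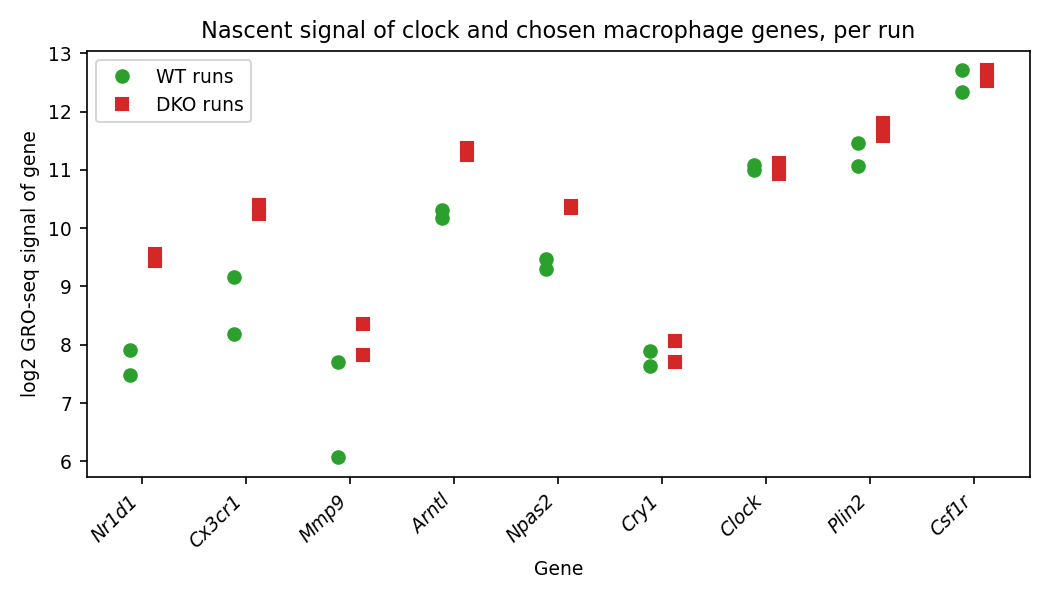
Log2 GRO-seq signal of 9 named genes in the 2 WT runs (circles) and the 2 DKO runs (squares). The DKO runs of Nr1d1, Cx3cr1, Arntl and Npas2 lie well above both WT runs, the WT runs of Mmp9 lie far apart at 7.71 and 6.07, and the runs of Cry1, Clock and Csf1r overlap.

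The lists fixed in advance were compared with random lists of genes of the same size and similar level from the same table. The 15 macrophage transcription factors had a median difference of 0.17 in the library labelled DKO, higher than 99.9% of 10000 random lists. Both DKO runs lay above both WT runs for 3 of them, below for 1, and overlapped for 11. Both DKO runs lay above for a similar share of all genes, 224 of 1220. The 26 peaks of these factors had a median GRO-seq difference of -0.03 (percentile 14.2 among random genes with as many peaks). Only the clock list was recomputed with runs left out, so the 99.9% was not checked against the spread between runs. Hif1a had -0.21, while Fos had 0.37, which was -0.03 without DKO run 2 and 0.76 without DKO run 1. The 10 protease genes had a median of 0.20, higher than 99.5% of random lists, with 0.24 for Adam17 and -0.19 for Plaur beside Mmp9. Their 13 peaks had a median GRO-seq difference of 0.31, at percentile 97.52 of random genes with as many peaks and just outside the central 95%. The 8 clock genes had a median of 0.17, at the 96.0th percentile and within the central 95%, and their 13 peaks a median GRO-seq difference of 0.51, at the 99.9th percentile of random genes with as many peaks. Without Nr1d1, the 10 other clock peaks had a median of 0.44, at the 99.3rd percentile. Pattern recognition genes had a median of 0.15 (percentile 90.6), chemokine and receptor genes 0.08 (percentile 81.7) and lipid genes 0.06 (percentile 71.3). The surface list had 0.00 (percentile 27.9) and the cofactor list 0.00 (percentile 42.3). For 5'GRO-seq in RAW cells, the 14 peaks of pattern recognition genes had a median of 0.32, higher than in 99.6% of random sets of genes with as many peaks, and no other list lay outside the central 95%. The random lists and sets were not matched for binding strength. The percentiles describe these libraries and are not tests between conditions.

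Sites and genes were then set side by side. The 39 peaks of the 24 genes that were higher in the library labelled DKO had higher GRO-seq signal there at 33 peaks, with a median difference of 0.52. These genes were chosen on the same libraries, so this value is no separate test. The same peaks had a median 5'GRO-seq difference of -0.82 with tagged RevErbalpha, lower than in 99.9% of 10000 random sets of genes with as many peaks. These sets were not matched for binding strength, which the 5'GRO-seq difference followed. The percentile therefore cannot separate a link between the assays from binding strength. Without Nr1d1, Cx3cr1, Arntl, Npas2 and Mmp9, left out together, the 5'GRO-seq median was -0.26, against -0.25 in random sets. For 17 intergenic enhancer-like peaks of such genes, which do not overlap gene bodies by the authors' class, the 5'GRO-seq median was -0.45, within the central 95% of random sets. Across all 1544 peaks the GRO-seq difference had a Spearman correlation of 0.19 with that of the assigned gene, but peaks within genes or at their starts read the same RNA. It was 0.10 (interval 0.01 to 0.19) for the intergenic enhancer-like peaks and 0.33 for the other class. With the 5'GRO-seq difference at the same peak the correlation was -0.005.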

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

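The deeper runs alone, 4 binding groups, the runs left out or shifted, the named genes left out, the genes above the lower quartile of level, the intergenic peaks of higher genes, the random genes with as many peaks and the larger offset by class were chosen after the data were seen. The shares of enhancer-like peaks, the location of peaks by class, the binding of enhancer-like against other peaks, the 5'GRO-seq difference between binding groups, and the lists near peaks other than the surface and cofactor lists kept their direction and their side of the threshold or interval under every alternative run for them, except that enhancer-like peaks farther than 1 kb from a start had a lower median than the others (-0.15, permutation p = 0.072), which did not pass the threshold either. With an offset of 10, the median 5'GRO-seq difference was -0.16 (genic enhancer-like peaks -0.22), with 181 peaks lower and 34 higher by 1 or more for 5'GRO-seq and 0 lower and 3 higher for GRO-seq, and RevErbbeta exceeded RevErbalpha by 0.24. Above the lower quartile of signal, the counts were 176 lower and 41 higher for 5'GRO-seq and 13 lower and 29 higher for GRO-seq, from fewer peaks. In the stronger 772 peaks the Spearman correlation of the RevErbs was 0.55 and their median difference 0.38. These peaks were picked by the mean of both values, a choice that can by itself lower the correlation. With the deeper runs alone the values were 0.49 and 0.89, and the cause was not tested. Leaving out 1 GRO-seq run gave 33 to 67 higher and 17 to 27 lower genes and a median gene difference of 0.01 to 0.07, and genes above the lower quartile of level gave 7 and 1. The median of the clock list was 0.11 to 0.19 under its alternatives, for which no percentile was computed. Shifting the runs to the same median turned the median gene difference from 0.035 to -0.0225, which the shift itself brings about. Among peaks of the higher genes, the 5'GRO-seq median of -0.82 was -0.45 for intergenic enhancer-like peaks and -0.26 without 5 named genes, both within the range of random sets. The surface list was no longer past the threshold within 10 kb (10.5% of members, Fisher's exact, adjusted p = 0.094), with enhancer-like peaks (15.8%, 0.069) or with the stronger peaks (10.5%, 0.15), nor was the cofactor list within 50 kb (7.7%, 0.59) or with the stronger peaks (15.4%, 0.090), and within 10 kb its share was 0.0%, below that of all genes; fewer peaks enter these tests. Within 10 kb, 15.8% of common peaks had a neighbour. No paired analysis was possible because each group has 1 sample. Other overlap rules, the stricter peak lists per RevErb, the alternatives for peaks of 1 RevErb alone, all RevErb peaks in place of common ones and the motif window were not run. The shallow ChIP-seq runs limit the rank of single peaks.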

Other observations

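The comparisons of binding groups, of genes by number of peaks, of run splits over all genes, of gaps between run ranges and of the 2 assays with each other were chosen after the data were seen, and the offset of 10 before. With the offset of 1, the largest differences at single sites involved mainly genes outside the lists, and these sites were chosen after their values were seen. With tagged RevErbalpha, 5'GRO-seq differences were -5.30 at a peak assigned to Pak1ip1, -5.11 at Hnrnpl, -4.97 at Smpdl3a and -4.61 at P4ha2, and 3.26 at Fam171b and at Gipc2. The Pak1ip1 and Hnrnpl peaks held about 0 tags with tagged RevErbalpha, so their differences depend on the offset. With 10 added before the logarithm the order turned, with -3.71 at the Nr1d1 start, -3.51 at P4ha2, -3.19 at Smpdl3a, -2.42 at Hnrnpl and -2.35 at Pak1ip1, and 1.95 at Fam171b and 0.99 at Gipc2. In the library labelled DKO, GRO-seq differences at peaks were 2.03 at Dnttip2, 2.00 at Ccnjl and 1.77 at Tgm2, and -1.57 at Itgav and -1.55 at Heatr6. With the larger offset these were 1.16 at Dnttip2, 0.40 at Ccnjl, 0.43 at Tgm2, -0.28 at Itgav and -0.49 at Heatr6, and the only other sites at 1 or above were peaks of the listed genes Nr1d1 (1.30) and Cx3cr1 (1.06). A site and its assigned gene could differ: Ccnjl had a peak difference of 2.00 and a gene difference of -0.74, which was -0.28 without DKO run 1 and -1.20 without DKO run 2, and Dnttip2 had 2.03 and -0.10. The 54 genes with 3 common peaks had a median gene difference of 0.12, against 0.03 for the 982 genes with 1 peak and 0.01 for the 12 genes with 4 or more.

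The 5'GRO-seq signal at common peaks was lower with tagged RevErbalpha, and more so with stronger binding. A single scaling factor for the whole library would leave no difference between strongly and weakly bound groups, which was -0.50. The shallower library and the offset before the logarithm matter least where signal is high, and in the 4th of 4 groups by signal the strongest minus the weakest binding group was still -0.32 (interval -0.52 to -0.08). Weak signal at strongly bound sites was tested by comparing binding groups within each signal group, and the difference was -0.1 or below in 3 of the 4 signal groups, the exception being the lowest. Repression at bound sites by RevErbalpha may account for the pattern, but with 2 5'GRO-seq libraries a difference between the 2 cell populations that does not come from RevErbalpha cannot be told apart from it.

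The genes that differed in the library labelled DKO were weighed against the spread between runs. The splits that mix genotypes gave a mean of 35.5 genes with a difference of 0.5 or more, against 33 for the real split, and among the 915 genes above the lower quartile of level a mean of 7.5 against 8, so the spread between runs may produce counts of this size. Genes whose run ranges lay 0.5 or more apart numbered 13 in the real split and at most 8 in the mixed ones. The largest gap between run ranges was 1.53 in the real split, for Nr1d1, and 1.0 in a mixed one, and above the lower quartile of level 5 genes in the real split against 0 and 1 had such gaps, with largest mixed gaps of 0.40 and 0.51. The 3 splits are too few to weigh single genes, and a biological explanation stays open for the 5 genes above the lower quartile, Nr1d1, Cx3cr1, Arntl, Npas2 and Slc15a3, whose gaps were 1.53, 1.08, 0.94, 0.87 and 0.70, while the gaps of 0.86 for Tspan33 and Tpd52l1 are of genes with little signal, where mixed splits reached 1.0.

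The differences in the library labelled DKO and those with tagged RevErbalpha did not correlate across the common peaks as a whole. Of 52 peaks higher by 1 or more in the library labelled DKO, 18 were lower by 1 or more with tagged RevErbalpha, where independent lists give 10.4. Another 3 of the 52 were higher by 1 or more with tagged RevErbalpha, as were 76 of all 1544 peaks. The 10.4 takes no account of binding. From the weakest to the strongest of the 5 binding groups, the 52 higher peaks numbered 11, 7, 7, 9 and 18. The 309 lower ones numbered 39, 38, 53, 63 and 116, in groups of 307 to 312 peaks. Whether binding accounts for the difference between 18 and 10.4 was not tested. The 52 also depended on the offset, since 3 peaks reached 1 when 10 was added before the logarithm. If few tags per site hid a relation, it could appear among the 387 sites with the most signal in both assays. There the Spearman correlation was -0.051 (interval -0.15 to 0.04). These sites cannot settle the point, since the counting error of the GRO-seq values is unknown. The 5'GRO-seq differences also varied with signal: the strongest binding group had medians of -0.44, -1.1, -0.73 and -0.32 from the lowest to the highest signal group. The assays differ in cell type, in the protein changed and in the RNA ends read, and these were not tested.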
